A study of Drosophila melanogaster with 18 samples.

How the data were processed

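The study measured ac4C in RNA of whole 3rd-instar larvae of Drosophila melanogaster in 3 genotypes, with 3 biological replicates each. Per the labels' protocols, eggs were laid over 24 h at 18 °C, and larvae of the first instar were moved to 30 °C, since GAL80 blocks the driver at the lower temperature. RNA came from 40 larvae per sample. Polyadenylated RNA was broken into pieces of about 100 nt, 10% was kept as input, and the rest was incubated with an ac4C antibody for 2 h. Libraries carried a molecular identifier of 12 bases and were read as pairs of 150 bases. The sources used here do not say how identifiers were used in the counts, so counting intervals would cover counting error only.

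The submitters' processing notes name fastp 0.23.1, STAR 2.7.6a, featureCounts of Subread 1.5.1, bedtools 2.30.0, deepTools 3.5.1, HOMER 4.9.1 and the build BDGP6, without saying which did what. The peak caller, the tool behind the differential tables and the strand setting of the counting are not given in the sources used here. Per the file headers, the deposited gene table holds FPKM per gene and input library. Deposited tables of differential genes hold a log2 fold change and p-values with FDR per gene from the authors' comparison. Each deposited peak list holds, per the file headers, the authors' fold enrichment, a ratio, with a p-value and FDR per peak, 1 list per genotype. The deposited tables of differential peaks hold read counts per peak and library for input and IP, with the authors' log2 change, p-value and FDR. From the values, listed peaks have a p under 0.05 and a log2 change of at least 1 in size. The 12 columns of per-library values in the deposited tables of differential genes were not used.

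Each FPKM value times the gene length was a whole multiple of 1 step per library (100% of values within 0.1 of a whole read), which gave the reads per gene. Depth was 17291110 to 19223499 reads in genes in the control input libraries, 17076581 to 24272099 in those labelled NAT10 RNAi and 15518179 to 21848490 in those labelled NAT10 and Xrp1 RNAi. Replicates differed by more than sampling noise (chi-square per degree of freedom over genes with at least 40 reads: 1.86 to 3.95 in control, 1.41 to 1.85 in NAT10 RNAi and 3.3 to 11.65 with both constructs), so each was kept as a sample. Replicate 1 with both constructs gave the values of 8.15 and 11.65, against replicates 2 and 3, and its median-ratio scale factor was 0.924, against 0.983 and 0.977 for those. Of the listed genes 12242 matched the reference annotation of the same assembly, 90.5% of them with the same span.

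Levels were tested with limma 3.58.1 in R 4.3.3 (trend and robust settings on) on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 3 input libraries. All 9 input libraries entered 1 fit with a mean per genotype and no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A count test is not the main test of FPKM values. As alternatives, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads and called 7860, 5249 and 6945 genes (edgeR) and 6977, 4265 and 5993 genes (DESeq2) in the comparisons of NAT10 RNAi with control, both constructs with control, and both constructs with NAT10 RNAi. Standard errors and p-values reflect the spread between biological replicates, 3 per group, pooled over the 3 genotypes. A genotype with a wider spread, as with both constructs, is thus tested partly against the narrower spread of the others. With only the 2 compared genotypes in the fit, limma called 8008, 4084 and 6845 genes in the same order.

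There were 34 gene lists, of which 33 had at least 3 tested members. They were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists. Camera called 15, 19 and 12 lists in the comparisons in the order above. With an estimated correlation 1, 0 and 4 remained: the ecdysone response list in NAT10 RNAi against control, and the lists of proteasome, ecdysone response, heat shock and p53 genes between both constructs and NAT10 RNAi. Fry, which does not compare a list with other genes, gave 32, 24 and 30. Libraries were also rescaled by the median ratio of their values.

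The gene lists, the terms of the limma fit and the rule for named genes were fixed before the data were examined. The rule takes both targets and the 5 genes with the largest fold in each direction among called genes without overlap between groups and with a mean of at least 5 FPKM in the higher group. It adds up to 4 called members of each list that was called or had at least 3 called members, and the lists of stage and tissue by counts. For peaks they are those of the targets and the 5 of largest fold in each direction per table. Of the 21 genes named as targets or by size, 5 share exon bases with another gene.

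The fitting step was tested on simulated data with known changes in 200 genes. Of changes of 1.5, 2 and 4-fold it recovered 77.6%, 94% and 98.5% for NAT10 RNAi against control, 85.1%, 89.6% and 98.5% for both constructs against control, and 77.6%, 92.5% and 98.5% between the RNAi genotypes, with 9, 8 and 6 false calls among 11447, 11442 and 11441 genes. The simulated genotypes had no shift of all genes and the same spread per gene. The real libraries differ in both, so these rates need not hold for them.

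Peaks were compared with bedtools 2.31.1 at a minimum overlap of 1 bp on the same strand, and placed by the annotation in the order coding sequence, 3' UTR, 5' UTR and noncoding exon. From each list 1 peak with a damaged chromosome name was left out. Change of input reads in a peak was scaled by the totals of the input libraries, after adding 0.5 reads, and the change of IP reads was left unscaled. Python 3.11.15 with scipy 1.17.1 gave the permutation tests (two-sided, 100000 resamples). IP libraries outside the listed peaks were not analysed here, so IP against input could not be fitted across all genes, and a sequence analysis of peaks was not run because genome sequence was not used here. Alternatives tried were other pseudocounts (0.1 and 5), no filter and a filter at 5 FPKM, rescaling and quantile normalization, a replicate block, other fits, each library left out, stricter peak thresholds and a 50% overlap of both peaks.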

Results

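Transcripts of whole 3rd-instar Drosophila melanogaster larvae were profiled by antibody capture of N4-acetylcytidine (ac4C), a modified base of RNA, followed by sequencing (ac4C-RIP-seq). There were 3 genotypes. The control carried the driver alone, and the next carried an RNAi construct against NAT10, the acetyltransferase that makes ac4C. The last carried constructs against NAT10 and against Xrp1, a stress-induced transcription factor of the bZIP family. Each genotype had 3 biological replicates, and each replicate gave an input library and an immunoprecipitated (IP) library, 18 libraries in all. Larvae of the control were taken at 72 h and those of NAT10 RNAi, which developed slowly, at 120 h. Harvest time therefore goes with genotype in this comparison. The harvest time of larvae with both constructs is not given in the labels. Input libraries held between 15518179 and 24272099 reads in genes.

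The targeted genes were examined first. The transcript of NAT10 (l(1)G0020, FBgn0027330, BDGP6 X:8716713-8720277, minus strand) was not lower in either RNAi genotype. It stood at 5.13, 4.97 and 5.46 FPKM in the control libraries, at 5.22, 5.93 and 5.76 in the libraries labelled NAT10 RNAi, and at 6.18, 6.04 and 6.02 in the libraries labelled NAT10 and Xrp1 RNAi. Its log2 fold change against control was 0.10 ± 0.06 (SE; limma, Benjamini-Hochberg adjusted p = 0.166) for NAT10 RNAi, and was -0.07 when libraries were rescaled to a common median ratio. For both constructs together it was 0.20 ± 0.06 (limma adjusted p = 0.025), in the direction opposite to the label. That call was lost without control replicate 1 (limma adjusted p = 0.0626) or 2 (0.0872). It was also lost without replicate 1 (0.0509) or 2 (0.0514) of the larvae with both constructs, and by DESeq2 (adjusted p = 0.0534). Between the RNAi genotypes the gene differed by 0.10 ± 0.06 (limma adjusted p = 0.193), and by 0.26 after rescaling, which passed the test (limma adjusted p = 0.00564). The gene shares 234 bp of exon with CG1785 on the opposite strand, whose reads may be counted with it. Transcript level therefore does not check the NAT10 label, and groups are named below by their labels. Xrp1 (FBgn0261113, 3R:18914968-18926849, plus strand) stood at 211 ± 2.82 FPKM in control (SD, n = 3), at 385.5 ± 0.925 in the libraries labelled NAT10 RNAi, and at 41.7 ± 1.85 in those labelled NAT10 and Xrp1 RNAi. It was thus 1.82-fold higher in the former and 4.96-fold lower in the latter than in control (limma adjusted p = 8.46e-09 and 2.31e-11).

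**Figure D1:**
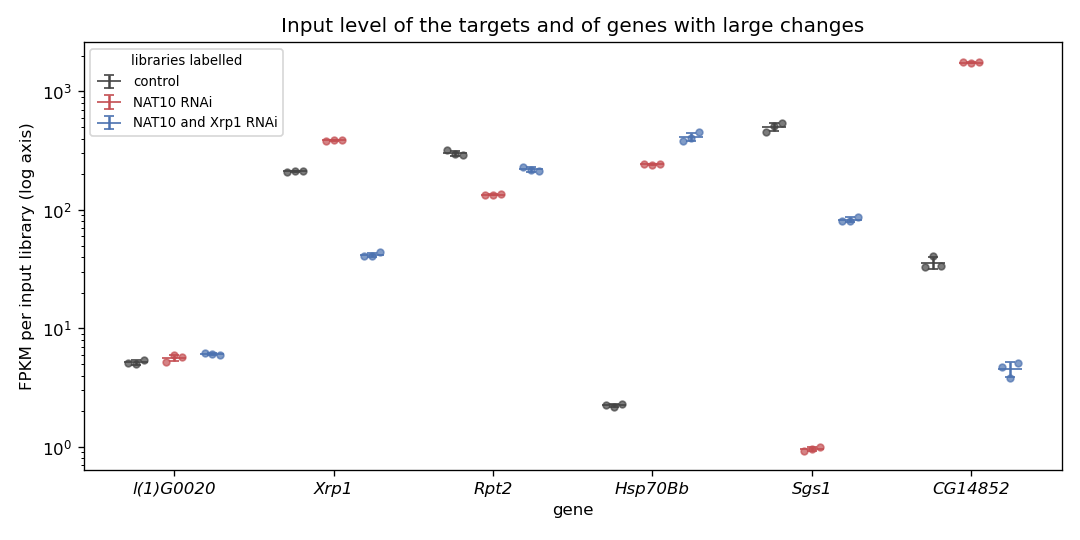
FPKM (log axis) of 6 genes in each of the 9 input libraries, grouped by the genotype on the label. Points are libraries, horizontal marks the mean and bars the SD of 3 libraries, and l(1)G0020, the NAT10 gene, lies between 4.97 and 6.18 FPKM in all 9, while Xrp1 is at 384.6 or more in those labelled NAT10 RNAi and at 43.85 or less in those labelled NAT10 and Xrp1 RNAi.

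The first comparison asked what changes in the transcriptome of larvae labelled NAT10 RNAi. Salivary glue genes, which encode the secretion that fixes the pupa to its substrate, were among those that fell furthest. Sgs1 dropped from 501.8 ± 43.3 FPKM to 0.962 ± 0.031 (SD, n = 3; 256-fold on the log2(FPKM + 1) scale), Sgs3 from 6481 to 285.5, Sgs7 from 2698 to 111.3 and Sgs8 from 196.4 to 6.23. Of 16 tested glue and gland genes 11 fell and 5 rose (limma; the same counts adjusted over the list alone), with a median log2 fold change of -1.83 (camera adjusted p = 3.22e-05 and adjusted p = 0.0776 with an estimated correlation). Genes that respond to ecdysone, the moulting hormone, were mostly lower: 19 of 23 fell and 3 rose (19 and 3 adjusted over the list alone; camera adjusted p = 5.73e-12 and adjusted p = 0.0353 with an estimated correlation). Examples were ImpE2 at -3.49, Eip78C at -2.79, Hr4 at -2.64 and E23 at -2.05 on the log2 scale. Of 9 ecdysone synthesis genes 6 fell and none rose (7 fell adjusted over the list alone; camera adjusted p = 0.000329 and adjusted p = 0.0673 with an estimated correlation). Examples were spok at -2.15 and phm at -0.85. These stage lists move together with the harvest at 72 h for control and 120 h for NAT10 RNAi. After rescaling the medians of the glue and ecdysone response lists were -2.01 and -0.86.

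Proteasome genes, whose products degrade tagged proteins, were lower. Of 35 subunit genes 32 fell and none rose (32 adjusted over the list alone), led by Rpt2 at -1.15, Rpn5 at -1.08, Prosbeta4 at -1.06 and Prosbeta2 at -1.01, and the median of the list was -0.76 (camera adjusted p = 2.23e-21 and adjusted p = 0.0532 with an estimated correlation). Among heat shock genes 8 of 19 rose and 9 fell (8 and 9 adjusted over the list alone, 8 and 11 after rescaling; camera adjusted p = 0.0603). Hsp70Bb rose by 6.23 on the log2 scale, from 2.25 to 242.1 FPKM, while the small chaperone genes Hsp23 and Hsp27 fell by 2.01 and by 1.88. The Hsp70 genes are near-identical copies, so the share of reads given to each is uncertain.

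DNA damage and JAK/STAT genes were higher in the libraries labelled NAT10 RNAi. In the list of p53 and DNA damage genes 10 of 12 rose and none fell (11 adjusted over the list alone; 6 after rescaling), including Ets21C at 1.42 (it shares 1532 bp of exon with nAChRbeta3 on the opposite strand), mre11 at 0.99 and Ku80 at 0.88 (camera adjusted p = 0.0108 and adjusted p = 0.125 with an estimated correlation). In the JAK/STAT and Turandot list 6 of 8 rose and none fell (6 adjusted over the list alone, and 6 higher with 2 lower after rescaling; camera adjusted p = 0.0281 and adjusted p = 0.15 with an estimated correlation). Examples were TotC at 2.77, upd1 at 1.47, upd3 at 1.33 and TotA at 1.10. Ilp8, a relaxin-like hormone that delays pupariation, rose by 2.38 on the log2 scale, from 0.171 ± 0.167 to 5.05 ± 0.289 FPKM (SD, n = 3; limma adjusted p = 5.46e-08). Of the 16 genes listed as Xrp1 partners and responses, a list that holds Xrp1 itself, 9 rose and 4 fell (10 and 4 adjusted over the list alone, 8 and 4 after rescaling), which the set test did not call (camera adjusted p = 0.51). Of 25 glutathione S-transferase genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, 12 and 4 after rescaling; camera adjusted p = 0.167), and of 13 JNK and wound genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, 6 and 4 after rescaling; camera adjusted p = 0.51).

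Muscle, blood cell, gut and detoxification genes were higher. Of 19 muscle genes 17 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 1.91e-05 and adjusted p = 0.131 with an estimated correlation). Mhc, the muscle myosin heavy chain gene, went from 116.4 to 474.1 FPKM. Of 13 hemocyte genes 11 rose and none fell (11 adjusted over the list alone; camera adjusted p = 0.000253 and adjusted p = 0.366 with an estimated correlation). Examples were Ppn at 2.20, Hml at 2.09, Col4a1 at 1.79 and vkg at 1.72. Of 47 digestive enzyme genes 32 rose and 4 fell (32 and 5 adjusted over the list alone, 31 and 9 after rescaling), the starch and sugar enzymes Amy-p and Mal-A3 by 3.36 and 3.27, of which Amy-p has a near-identical copy, Amy-d, that makes its share uncertain (camera adjusted p = 0.00353 and adjusted p = 0.7 with an estimated correlation). Of 55 cytochrome P450 genes 43 rose and 3 fell (45 and 3 adjusted over the list alone; camera adjusted p = 0.000244 and adjusted p = 0.197 with an estimated correlation). Examples were Cyp6a23 at 3.43 and Cyp4e3 at 2.97. Imaginal disc patterning genes went the other way: 9 of 19 fell and 2 rose (9 and 2 adjusted over the list alone, and 15 lower with 2 higher after rescaling; camera adjusted p = 0.0015 and adjusted p = 0.0732 with an estimated correlation). Examples were hth at -0.82 and vg at -0.72. These tissue lists, too, move together with the 72 h and 120 h harvests.

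Lists of ribosomal protein, ribosome biogenesis, oxidative phosphorylation and tRNA synthetase genes were called higher at the preset correlation. Of 84 cytosolic ribosomal protein genes 67 rose and 1 fell (68 and 1 adjusted over the list alone; median log2 fold change 0.31, or 0.11 after rescaling; camera adjusted p = 0.00107 and adjusted p = 0.7 with an estimated correlation), and after rescaling 40 rose and 8 fell. Of 53 ribosome biogenesis genes 37 rose and 4 fell (38 and 4 adjusted over the list alone), with Non1 at 1.46 (camera adjusted p = 0.0113 and adjusted p = 0.131 with an estimated correlation); after rescaling 29 rose and 8 fell. Of 84 oxidative phosphorylation genes 62 rose and 2 fell (62 and 2 adjusted over the list alone), with SdhA at 1.10 and Cyt-c1 at 1.06 (camera adjusted p = 0.000489 and adjusted p = 0.525 with an estimated correlation); after rescaling 47 rose and 8 fell. Of 20 tRNA synthetase genes 17 rose and none fell (17 adjusted over the list alone, 10 after rescaling; camera adjusted p = 0.0281 and adjusted p = 0.679 with an estimated correlation), a list call that ended on rescaling (adjusted p = 0.0745).

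Further stage and tissue lists were not called by the set test in this comparison. In the late-larval fat body list 6 of 14 rose and 6 fell (camera adjusted p = 0.51), with the fat body receptor gene Fbp1 at -2.30. Larval cuticle genes had 22 higher and 17 lower of 49 (camera adjusted p = 0.491), and both tested Eig71E genes were lower. Neuron genes had 8 higher and 3 lower of 18 (adjusted p = 0.966), testis genes 11 and 1 of 16 (0.159), germline genes 2 and 1 of 4 (0.676), tracheal genes 6 and 3 of 11 (0.951), Malpighian tubule genes 4 and 1 of 7 (0.336), and midgut and peritrophic matrix genes 6 and 1 of 10 (0.336), all by camera. Genes of antimicrobial defence had 11 higher and 4 lower of 19 (0.676), of ATF4 and integrated stress 8 and 8 of 18 (0.376), of insulin and starvation 7 and 6 of 17 (0.51), and of the cell cycle 9 and 9 of 37 (0.088, or 0.0433 after rescaling). Mitochondrial ribosomal protein genes had 32 higher and 2 lower of 70 (0.295), and translation factor genes 29 and 5 of 49 (0.336), which became 16 and 16 after rescaling. Rescaled counts, higher and then lower, were 3 and 17 for the cell cycle, 15 and 6 for mitochondrial ribosomal proteins, 6 and 8 for neuron, 4 and 5 for tracheal, 3 and 2 for Malpighian tubule and 6 and 2 for midgut genes. They were 5 and 9 for ATF4, 5 and 7 for insulin, 18 and 20 for cuticle, 6 and 8 for fat body, 10 and 4 for antimicrobial and 10 and 1 for testis genes. Adjusted over the list alone, the counts of these lists without rescaling were the same except for cuticle (24 higher), fat body (7 lower), ATF4 (9 higher) and mitochondrial ribosomal protein genes (30 higher). Among uncalled lists, the median, the mean and the direction of the set test differed in sign for the lists of ATF4 and integrated stress, heat shock, larval serum and fat body, larval cuticle, insulin and starvation, neuron and germline genes, and rescaling turned the sign of the median for ATF4, insulin, neuron and tracheal genes.

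Across all 11557 genes tested, 7653 differed between the libraries labelled NAT10 RNAi and control (limma, Benjamini-Hochberg adjusted p under 0.05), 5468 higher and 2185 lower, and 827 of them by at least 2-fold (586 higher, 241 lower; 419 and 351 after rescaling). That count was 419 with a pseudocount of 5 and 1277 by edgeR. The median of all genes was 0.17 higher on the log2 scale, so small rises are to be read against that shift. After rescaling by the median ratio 3697 genes were higher and 3642 lower, so the share of calls that were higher went from 71.4% to 50.4%. The genes with the largest rises were CG14850, CG14852, CG13135 and Nplp2 besides Hsp70Bb: CG14850 went from 0.249 to 249.7 FPKM and CG14852 from 35.8 to 1751. Besides the glue genes, the largest falls were in CG7906, from 204.7 to 3.80 FPKM, and CG13606, from 130.6 to 3.65. CG14852 shares 82 bp of exon with CG31313 on the opposite strand. Further named genes share exon bases with a neighbour and are uncertain for that reason: Hr4 (46 bp), Prosbeta2 (82 bp), Prosbeta3 (19 bp), Prosbeta4 (20 bp), Rpt2 (116 bp), SdhA (38 bp), Irbp18 (95 bp), mre11 (9 bp), Hsp27 (49 bp), Ilp8 (26 bp) and hth (207 bp).

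The next comparison asked what differs from control when RNAi against Xrp1 is added. Glue genes were low here too: Sgs3 stood at 294.7 ± 12.3 FPKM against 6481 ± 691.7 in control (SD, n = 3), Sgs8 at 6.48 against 196.4 and CG7587 at 1.51 against 171.9, while Sgs1 stood at 82.7 FPKM. Of 16 glue and gland genes 11 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 6.1e-06 and adjusted p = 0.0905 with an estimated correlation), and both Eig71E genes fell. Of 23 ecdysone response genes 10 were lower and 4 higher (11 and 4 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0403 and adjusted p = 0.251 with an estimated correlation). That call ended without control replicate 2 (0.0521) and without replicate 2 (0.0963) or 3 (0.088) of the larvae with both constructs. It also ended after rescaling (0.0532) and with no filter on low values (0.0563). Of 9 ecdysone synthesis genes 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.027 and adjusted p = 0.172 with an estimated correlation). For the stage and tissue lists of this comparison the harvest time of control was 72 h, and that of larvae with both constructs is not given in the labels.

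Of the called lists, those of DNA damage genes and of Xrp1 partners both hold Xrp1 itself, the target. Of 12 p53 and DNA damage genes 5 fell, 1 rose and 6 did not pass (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.019 and adjusted p = 0.153 with an estimated correlation). The falls included Xrp1 itself at -2.31, Gadd45 at -0.79 and rpr at -0.52. Of the 16 Xrp1 partners and responses 8 fell, Xrp1 among them, 4 rose and 4 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.0457 and adjusted p = 0.251 with an estimated correlation). Examples were Thor at -1.31 and Irbp18, the dimerisation partner of Xrp1, at -0.50. The call ended without control replicate 3 (0.0672), without NAT10 RNAi replicate 1 (0.0513), without replicate 2 (0.0654) or 3 (0.0571) of the larvae with both constructs, and after rescaling (0.0532). Ilp8 stood at 0.167 ± 0.152 FPKM against 0.171 ± 0.167 in control (SD, n = 3; limma adjusted p = 0.989) and upd3 at 0.414 against 0.330 (limma adjusted p = 0.483). Proteasome genes were lower by less than in the first comparison, with 21 of 35 lower and 3 higher (23 and 5 adjusted over the list alone) and a median of -0.22 (camera adjusted p = 3.8e-05 and adjusted p = 0.251 with an estimated correlation). Among heat shock genes 10 of 19 rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.0171 and adjusted p = 0.142 with an estimated correlation). Examples were Hsp70Bb at 6.99 and Hsp70Ba at 3.37, both among the near-identical Hsp70 copies. The 13 members other than those copies had 4 higher and 6 lower, with a median of 0.03. These other members therefore showed no rise as a set, though 4 of them were higher.

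Muscle genes were higher again, with 17 of 19 up and none down (17 adjusted over the list alone) and Mhc at 403.8 FPKM (camera adjusted p = 1.23e-13 and adjusted p = 0.0905 with an estimated correlation). Of 47 digestive enzyme genes 31 rose and 2 fell (33 and 2 adjusted over the list alone; camera adjusted p = 2.15e-09 and adjusted p = 0.316 with an estimated correlation). Examples were Amy-p at 2.66 and Mal-A4 at 2.62. Of 19 antimicrobial and immune genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00158 and adjusted p = 0.0905 with an estimated correlation). Examples were PGRP-SC1a at 2.88, AttD at 2.63 and DptA at 1.62. Larval cuticle genes had 24 higher and 8 lower of 49 (28 and 8 adjusted over the list alone; camera adjusted p = 0.000261 and adjusted p = 0.251 with an estimated correlation). Examples were Lcp65Ab1 at 2.20 and Lcp65Ab2 at 2.14, near-identical neighbours whose shares are uncertain. Late-larval fat body genes had 9 higher and 4 lower of 14 (9 and 4 adjusted over the list alone; camera adjusted p = 0.016 and adjusted p = 0.475 with an estimated correlation). Lsp1gamma, which encodes a storage protein, stood at 857.6 FPKM against 450.2.

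Further lists were called. Hemocyte genes had 7 higher and 1 lower of 13 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0147 and adjusted p = 0.443 with an estimated correlation), cytochrome P450 genes 23 and 7 of 55 (24 and 7 adjusted over the list alone; adjusted p = 0.019 and adjusted p = 0.388 with an estimated correlation), and midgut and peritrophic matrix genes 4 and 1 of 10 (4 and 1 adjusted over the list alone; adjusted p = 0.0457 and adjusted p = 0.443 with an estimated correlation). The midgut call ended without control replicate 2 (0.0657), without NAT10 RNAi replicate 2 (0.0506) and without replicate 2 (0.0607) or 3 (0.088) of the larvae with both constructs. Oxidative phosphorylation genes had 30 higher and 4 lower of 84 (30 and 4 adjusted over the list alone; camera adjusted p = 0.00507 and adjusted p = 0.443 with an estimated correlation), and ribosome biogenesis genes 22 and 6 of 53 (24 and 6 adjusted over the list alone; adjusted p = 0.00574 and adjusted p = 0.14 with an estimated correlation). Lower lists were imaginal disc patterning, with 9 of 19 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00507 and adjusted p = 0.104 with an estimated correlation), and neuron genes, with 8 of 18 lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.0147 and adjusted p = 0.251 with an estimated correlation). The neuron gene brp, for a protein of the synaptic active zone, was at -1.60. Testis genes had 3 higher and 6 lower of 16 (camera adjusted p = 0.755), germline genes 1 and 1 of 4 (0.755), tracheal genes 5 and 2 of 11 (0.115) and Malpighian tubule genes 2 and 1 of 7 (0.583, and 2 and 2 after rescaling). Glutathione S-transferase genes had 8 higher and 4 lower of 25 (0.848), ATF4 genes 2 and 7 of 18 (0.115), JNK and wound genes 1 and 6 of 13 (0.0809, or 0.047 without control replicate 1), JAK/STAT and Turandot genes 1 and 2 of 8 (0.987), insulin and starvation genes 2 and 7 of 17 (0.105) and cell cycle genes 7 and 7 of 37 (0.713). Cytosolic ribosomal protein genes had 14 higher and 20 lower of 84 (0.411), mitochondrial ones 16 and 6 of 70 (0.412), translation factors 8 and 12 of 49 (0.345) and tRNA synthetases 5 and 3 of 20 (0.848), none of them called by camera. Adjusted over the list alone, counts of uncalled lists differed for Malpighian tubule (2 lower), glutathione S-transferase (5 lower), insulin (3 higher), translation factor (9 higher) and mitochondrial ribosomal protein genes (14 higher, 4 lower). For testis and for JAK/STAT and Turandot genes, neither called, the median and the set test differed in sign.

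In this comparison 4710 of 11557 genes differed from control (limma adjusted p under 0.05), 2490 higher and 2220 lower, 197 of them by at least 2-fold (137 higher, 60 lower). The 2-fold count was 325 with a pseudocount of 0.1, 105 with 5, and 380 by edgeR. The median of all genes moved by 0.001. Replicate 1 of the larvae with both constructs stood apart from its group: its input reads differed from those of replicates 2 and 3 by a chi-square per degree of freedom of 8.15 and 11.65, against 3.3 between those. Without it 4639 genes were called, 2677 higher and 1962 lower. Besides Hsp70Bb, the largest rises were in CG12522, from 0.0754 to 39.7 FPKM, CG32071, from 7.04 to 178.1, and CR43908 and CG15741, which share 394 bp of exon on opposite strands and cannot be read as separate changes. CR45210, from 85.4 to 10.4 FPKM, shares 263 bp of exon with nes on the opposite strand.

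The last input comparison set the libraries with both constructs against those labelled NAT10 RNAi, and so asked which levels differ when Xrp1 is also targeted. Ecdysone response genes were higher with both constructs, 17 of 23 up and 3 down (17 and 3 adjusted over the list alone; camera adjusted p = 8.45e-13 and adjusted p = 0.0147 with an estimated correlation). Examples were ImpE2 at 2.95, Eip78C at 2.59 and E23 at 2.12. Proteasome genes were higher, 31 of 35 up and none down (31 adjusted over the list alone; camera adjusted p = 2.6e-22 and adjusted p = 0.0319 with an estimated correlation). Prosalpha5 and Prosbeta3 were both at 0.93. So were heat shock genes, 15 of 19 up and 3 down (15 and 3 adjusted over the list alone, 15 and 1 after rescaling; camera adjusted p = 4.84e-10 and adjusted p = 0.0123 with an estimated correlation). Examples were Hsp23 at 1.65 and Hsp26 at 1.46. All 12 tested p53 and DNA damage genes were lower (12 adjusted over the list alone; 9 after rescaling; camera adjusted p = 0.000435 and adjusted p = 0.0491 with an estimated correlation). Examples were Xrp1, a member, at -3.18, Gadd45 at -1.39, Irbp at -1.14 and mre11 at -1.07. Because the harvest time of larvae with both constructs is not given in the labels, a difference in stage between these groups is open.

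Hemocyte genes were lower, with 12 of 13 down and none up (12 adjusted over the list alone; camera adjusted p = 0.00016 and adjusted p = 0.325 with an estimated correlation). Examples were Ppn at -1.69 and Hml at -1.41. Cytochrome P450 genes had 38 lower and 1 higher of 55 (38 and 1 adjusted over the list alone, 31 and 7 after rescaling), with Cyp6a23 at -3.67 (camera adjusted p = 0.00277 and adjusted p = 0.325 with an estimated correlation), and JAK/STAT and Turandot genes 6 lower and 1 higher of 8 (6 and 1 adjusted over the list alone, 5 and 2 after rescaling; camera adjusted p = 0.0353 and adjusted p = 0.182 with an estimated correlation; 0.0535 with a pseudocount of 0.1). TotC was at -2.63. Ilp8 fell by 2.38 on the log2 scale (limma adjusted p = 9.88e-08) and upd3 by 1.24. Of the 16 Xrp1 partners and responses 13 were lower, Xrp1 itself at -3.18 among them, and 3 higher (13 and 3 adjusted over the list alone; camera adjusted p = 0.0684, or 0.0126 after rescaling and 0.0422 without replicate 1 of the larvae with both constructs). Cytosolic ribosomal protein genes had 72 lower and none higher of 84 (72 adjusted over the list alone; camera adjusted p = 9.16e-05 and adjusted p = 0.585 with an estimated correlation), and after rescaling 40 lower and 7 higher. The tRNA synthetase genes had 14 lower and none higher of 20 (15 adjusted over the list alone, and 8 lower with 1 higher after rescaling; camera adjusted p = 0.0409 and adjusted p = 0.585 with an estimated correlation), a call lost on rescaling (0.0697), without NAT10 RNAi replicate 2 (0.0617) and without NAT10 RNAi replicate 3 (0.0574).

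Ecdysone synthesis genes had 5 higher and 2 lower of 9 (5 and 2 adjusted over the list alone, 7 and 1 after rescaling; camera adjusted p = 0.00531 and adjusted p = 0.107 with an estimated correlation). Among them spok was at 1.65. Larval cuticle genes had 23 higher and 16 lower of 49 (23 and 18 adjusted over the list alone; camera adjusted p = 0.000931 and adjusted p = 0.325 with an estimated correlation; 0.065 after rescaling), and antimicrobial genes 9 higher and 8 lower of 19 (9 and 8 adjusted over the list alone; adjusted p = 0.0409 and adjusted p = 0.182 with an estimated correlation; 0.297 after rescaling and 0.0551 without NAT10 RNAi replicate 3). Glue and gland genes had 5 higher and 7 lower of 16 (camera adjusted p = 0.339), and Sgs3 and Sgs8 did not differ by the test (limma adjusted p = 0.582 and 0.624), while Sgs1 was 5.41 higher on the log2 scale. Of the Eig71E pair 1 was higher. Fat body genes had 6 higher and 6 lower of 14 (adjusted p = 0.2), muscle genes 3 and 14 of 19 (0.2), neuron genes 1 and 10 of 18 (0.191), imaginal disc genes 6 and 5 of 19 (0.115), testis genes 1 and 10 of 16 (0.115), germline genes 1 and 0 of 4 (0.247), tracheal genes 3 and 4 of 11 (0.703), Malpighian tubule genes 0 and 4 of 7 (0.339), midgut and peritrophic genes 1 and 6 of 10 (0.81) and digestive enzymes 14 and 26 of 47 (0.745), all by camera and none called. Glutathione S-transferase genes had 3 higher and 17 lower of 25 (0.21), ATF4 genes 5 and 9 of 18 (0.838), JNK and wound genes 2 and 9 of 13 (0.0936, or 0.0472 after rescaling), insulin and starvation genes 2 and 10 of 17 (0.757) and cell cycle genes 5 and 10 of 37 (0.183). Oxidative phosphorylation genes had 3 higher and 50 lower of 84 (camera adjusted p = 0.0568). That list was called after rescaling (0.0472), with no filter on low values (0.0453), without control replicate 1 (0.0469) or 2 (0.0473), without NAT10 RNAi replicate 1 (0.0441), and without replicate 1 (0.0432) or 2 (0.0233) of the larvae with both constructs. Mitochondrial ribosomal protein genes had 0 higher and 27 lower of 70 (0.703), ribosome biogenesis genes 4 and 31 of 53 (0.289) and translation factors 4 and 27 of 49 (0.165). After rescaling these became 13 and 10, 12 and 9, and 16 and 16. Rescaling also gave 12 higher and 2 lower cell cycle genes, 10 and 0 imaginal disc, 7 and 5 insulin, 8 and 5 glue, 7 and 5 fat body, 4 and 8 neuron, 3 and 2 tracheal and 5 and 11 muscle genes. It gave 5 and 11 glutathione S-transferase, 5 and 7 ATF4, 3 and 8 JNK, 2 and 2 Malpighian tubule, 3 and 4 midgut, 18 and 20 digestive, 1 and 9 testis and 9 and 33 oxidative phosphorylation genes. Adjusted over the list alone, counts of uncalled lists differed for JNK (10 lower), mitochondrial ribosomal protein (23 lower), cell cycle (9 lower), muscle (4 higher) and imaginal disc genes (5 higher). Among uncalled lists the median, the mean and the set test differed in sign for ATF4, cell cycle, fat body, glue, digestive enzyme and tracheal genes. Rescaling turned the sign of the median for ATF4, cell cycle, fat body, glue, tracheal and neuron genes.

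Between these groups 7094 of 11557 genes differed (limma adjusted p under 0.05), 1761 higher and 5333 lower with both constructs, 512 of them by at least 2-fold (185 higher, 327 lower; after rescaling the split turned, with 263 higher and 234 lower). The 2-fold count was 830 with a pseudocount of 0.1, 234 with 5, and 854 by edgeR. Without replicate 1 of the larvae with both constructs, which stood apart, there were 6702, 1800 higher and 4902 lower. The median of all genes was -0.16 on the log2 scale, and after rescaling 3231 genes were higher and 3207 lower, so the share that was higher went from 24.8% to 50.2%. CG14852 was the gene with the largest difference, 4.56 FPKM against 1751, followed by CG14850, with 0.446 against 249.7, and CG8087, with 3.15 against 292.9. On the other side CG32071 stood at 178.1 FPKM against 2.94 and CG7906 at 154.8 against 3.80.

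Of the genes changed in the libraries labelled NAT10 RNAi, 4227 that were higher than in control were lower with both constructs than in NAT10 RNAi, where independent lists would share 2523.2, and 1250 that were lower than in control were higher, where independent lists would share 332.9. After rescaling these were 2500 (independent lists, 1025.9) and 2433 (1018.2), so the unequal numbers go with the shift of all genes. Across the 11557 genes the log2 fold changes of these comparisons had r = -0.791 and a covariance of -0.236, against -0.486 and -0.00384 for simulated unchanged groups that share libraries in the same way, a difference in covariance of -0.232. The comparisons of each RNAi genotype with control shared 1959 higher genes (independent lists, 1178.1) and 1198 lower genes (419.7), or 1592 (778) and 1689 (755.4) after rescaling, with r = 0.537 and a covariance of 0.116, against 0.504 and 0.00403 simulated, a difference in covariance of 0.112. Simulated unchanged groups shared 0 called genes on average, which follows from their being unchanged and sets no level for these overlaps. Genes are not independent replicates, and the first pair shares the NAT10 RNAi libraries and the other the control libraries. With 3 libraries each, neither could be split into parts of at least 2, so part of each excess may come from the shared libraries.

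**Figure D2:**
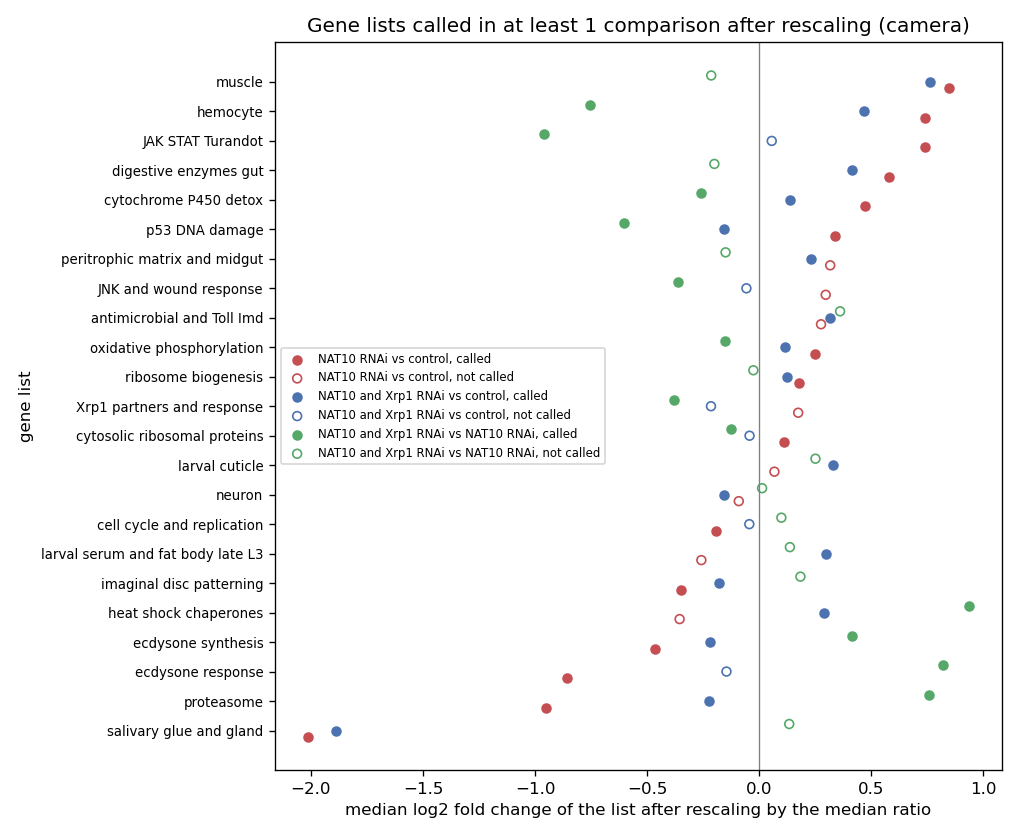
Median log2 fold change (x axis) of each gene list (y axis) called in at least 1 comparison after rescaling by the median ratio, with 1 point per list and comparison, filled where called by camera with the preset correlation. Proteasome and ecdysone response lists lie at -0.95 and -0.86 in NAT10 RNAi against control and at 0.76 and 0.82 in both constructs against NAT10 RNAi.

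The authors' deposited table of input genes for NAT10 RNAi against control lists 1261 genes, 740 higher and 521 lower, of which 1156 were tested here; all 1156 had the direction found here and 1155 were called. The authors' deposited table for both constructs against control lists 346 genes, 244 higher and 102 lower, and all 320 tested here were called in that direction. Of the genes called by limma with at least a 2-fold change, the authors' deposited tables list 757 of 827 and 197 of 197. The number with a 2-fold change was 1210 and 325 with a pseudocount of 0.1, and 1277 and 380 by edgeR.

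The antibody-enriched regions were compared next, under the labels as given, which the NAT10 transcript does not check. The authors' peak lists, 1 per genotype, held 31665 peaks for control, 31191 for NAT10 RNAi and 30886 for both constructs, covering 7.33, 6.95 and 6.96 Mb and lying in 10917, 10835 and 10615 genes. The median peak was 182 bp wide in each list, and the authors' median fold enrichment was 2.22, 2.07 and 2.18 (lower quartiles 1.68, 1.62 and 1.67). The authors' p, from a peak caller that is not named, reached 0.049 in each list. Their FDR reached 0.18, 0.185 and 0.185, so the lists include weakly enriched regions. Most peaks overlapped coding sequence (79.2% in control, 75.7% in NAT10 RNAi and 76.7% with both constructs), and 3940, 4690 and 4498 peaks lay in 3' UTRs. Of control peaks 70.6% overlapped a NAT10 RNAi peak by at least 1 bp and 69.8% a peak of the larvae with both constructs. In the other direction 72.7% and 72.1% overlapped a control peak. Between the RNAi lists the shares were similar, at 71.5% of NAT10 RNAi peaks and 71.8% of peaks with both constructs. Peaks not shared with control need not therefore be lost or gained with RNAi. At the level of genes 88.3% and 87.5% of control genes with a peak had one in the other lists. There is 1 list per genotype, so these differences have no replicate check.

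In the authors' deposited table of differential peaks for NAT10 RNAi against control, 1336 peaks in 1150 genes were listed, 320 higher and 1016 lower. For both constructs against control the authors' deposited table listed 1316 peaks in 1102 genes, 608 higher and 708 lower. Of these, 166 and 204 had an FDR under 0.05 in the authors' deposited tables. Over all listed peaks the median change in input reads was -1.29 on the log2 scale for higher and 1.65 for lower peaks in NAT10 RNAi, against 0.41 and -0.17 in IP reads. With both constructs it was -1.45 and 1.22 in input reads and 0.24 and -0.35 in IP reads. IP reads were not scaled for depth, so only the gap between higher and lower peaks can be read from them. That gap was 2.94 and 2.67 in input reads and -0.57 and -0.59 in IP reads for NAT10 RNAi and both constructs. For peaks with an FDR under 0.05 in the authors' deposited tables it was 2.96 and 2.54 in input and 0.17 and -0.26 in IP reads, and for peaks with at least 100 input reads 2.32 and 2.0 in input and 0.05 and -0.21 in IP reads. Their position differed with direction: 33.1% of higher peaks for NAT10 RNAi lay in 3' UTRs against 4.6% of lower ones, and 29.3% against 8.5% with both constructs. Lower peaks lay in coding sequence in 87.7% and 83.6% of cases, against 50.3% and 56.9% of higher peaks. By the medians above, input reads fell in higher peaks and rose in lower ones. These positions may therefore follow the input reads and need not be those of changed antibody capture, which was not tested. Both tables shared 226 genes with a lower peak, where independent lists would share 42.8, and 37 genes with a higher peak (independent lists, 12.5). The tables share the control libraries, to which part of the overlap may be due. Reads per library outside the listed peaks were not analysed here, so no overlap was simulated for unchanged groups.

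**Figure D3:**
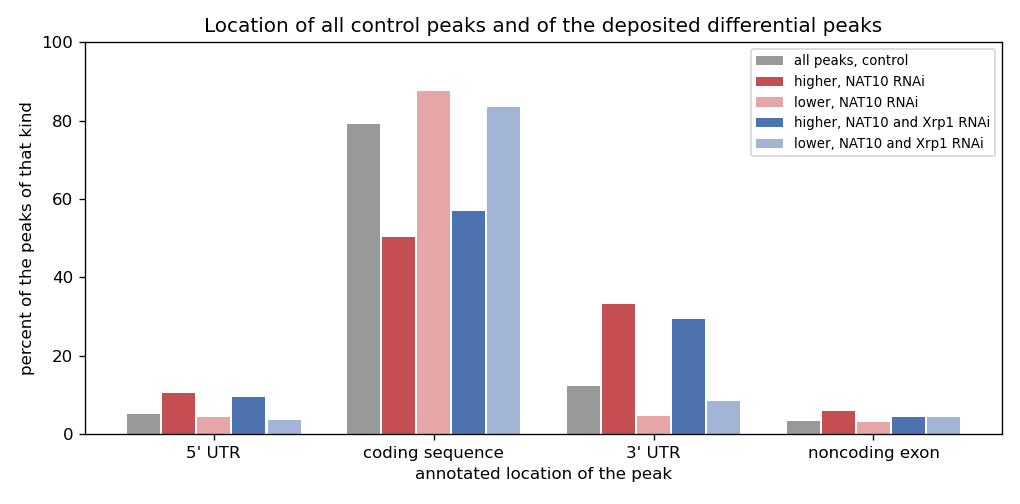
Percent of peaks (y axis) by annotated location (x axis) for all control peaks and for the higher and lower peaks of each deposited differential table. Higher peaks lie in 3' UTRs in 33.1% and 29.3% of cases and lower peaks in 4.6% and 8.5%, against 12.4% of all control peaks. By their medians, input reads fell in higher peaks and rose in lower ones.

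No peak of Xrp1 was in either table, and no peak of the NAT10 gene was in that for NAT10 RNAi. With both constructs the authors' deposited table listed 1 coding-sequence peak of l(1)G0020 (X:8718667-8718846, minus strand) as higher, with a log2 change of 2.78 and an FDR of 0.239. Its summed reads went from 134 to 35 in the IP libraries and from 31 to 1 in the input libraries. The peaks of largest fold were ties with no input read in one genotype. For NAT10 RNAi 6 peaks shared the highest log2 change of 8.24, among them peaks of CG42402, CG2065, Ih, hts and CG12531, and 8 shared the lowest of -9.99, among them peaks of CG34124, xit, mura, cac and Tehao. With both constructs 4 peaks shared 9.92 (CG14811, SMSr, Inos and CR44237), with ast at 9.77, and 6 shared -9.03, among them ine, CG8292, rib, Hsl and CAH14. They rest on few reads: the Tehao peak (2L:13438413-13438622) had 17 IP and 0 input reads in control against 24 and 15, and the CG2065 peak (2R:7664975-7665152) had 30 IP and 11 input reads in control against 19 and 0. These folds in the authors' deposited tables are therefore not sizes of change.

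Deeper peaks were then chosen by the smallest p, after the values above had been seen. The authors' deposited table gave a 5' UTR peak of Hsc70Cb, a chaperone gene (3L:14037048-14037257, plus strand), a log2 change of 1.15 for NAT10 RNAi (FDR 9.37e-32), with 4340 IP and 2950 input reads in control against 3260 and 1148. With both constructs the authors' deposited table gave that peak 1.07, with 3283 IP and 1062 input reads. A coding-sequence peak of hep, the kinase that activates JNK (X:13084330-13084570, minus strand), had 6162 IP and 1472 input reads in control, 4616 and 571 in NAT10 RNAi and 4494 and 524 with both constructs. Among lower peaks, a 3' UTR peak of His3.3B (X:9153649-9153858, minus strand) had a log2 change of -1.63 in the authors' deposited table, with 727 IP and 221 input reads in control against 557 and 604. A 3' UTR peak of IA-2 (2L:1012635-1012786, minus strand) had a log2 change of -1.32 there, with 2720 IP reads in control against 890 and 418 input reads against 400. With both constructs the peak with the smallest p in the authors' deposited table was a lower one in the coding sequence of the glue gene Sgs5 (3R:17595967-17596112, plus strand), with a log2 change of -1.13 and an FDR of 2.26e-45. Its IP reads went from 272080 to 23637 and its input reads from 71355 to 13263, which by reads not scaled for depth is a larger drop in IP than in input. A lower coding-sequence peak of exd (X:15993647-15994047, plus strand) had 1561 IP and 416 input reads in control against 1872 and 1046.

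Transcript changes were then compared with peak changes. In NAT10 RNAi against control the median input log2 fold change was 0.23 for 803 genes with lower peaks, 0.01 for 244 genes with higher peaks and 0.17 for 9423 genes with peaks but no listed change. With both constructs the medians were 0.06 for 544 genes, -0.07 for 468 genes and 0.003 for 9460 genes. Across genes, Spearman's rho between the peak change and the input change was -0.193 over 1047 genes and -0.21 over 1012 genes (permutation p = 1e-05 for both, the smallest that 100000 resamples can give). Over genes of at least 5 FPKM rho was -0.11 (p = 0.007) and -0.124 (p = 0.003). The input reads enter both values, and genes are not independent replicates.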

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

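The tests of transcript level and of counting error for the differential peaks were set out before their results were seen, and the other tests of this part were chosen afterwards. The p53 and DNA damage list drew attention because its median log2 fold change was 0.506 in NAT10 RNAi against control and -0.148 with both constructs against control. The difference itself was tested between the RNAi genotypes (camera adjusted p = 0.000435 and adjusted p = 0.0491 with an estimated correlation), and Xrp1, the gene targeted by the added construct, is a member of the list. The list was flagged for this difference, so the test restates it and adds no separate support.

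There were 7 genes at least 2-fold higher in NAT10 RNAi and at least 2-fold lower with both constructs than in control: CG14852, CG15784, CR44138, CG14265, CG33926, CG12310 and CG8087. Another 3 genes, Alp7, CG42500 and CG32071, were at least 2-fold lower in the former and higher in the latter. CG14852 stood at 35.8, 1751 and 4.56 FPKM in control, NAT10 RNAi and both constructs, and Alp7 at 51.9, 10.1 and 121.2 (limma adjusted p of the difference between the RNAi genotypes 1.57e-12 and 5.68e-12). These genes were chosen after their values were seen, and the counts are of values without rescaling. In NAT10 RNAi against control CG14265 and CG33926 were only 1.08 and 1.12 higher on the log2 scale, where the median of all genes was 0.17 higher. Their place among the 7 may therefore depend on scaling. No group had the 4 samples needed for a test of single outlying values, though over genes with at least 40 reads replicate 1 with both constructs stood apart from replicates 2 and 3 (chi-square per degree of freedom 8.15 and 11.65, against 3.3 between those).

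Differential peaks in the authors' deposited tables differed, by their medians, more in input than in IP reads. A change in the level of the whole gene is argued against as the source of most of the input difference in the listed peaks. The gap in gene-level change between genes with lower and higher peaks was 0.24 for NAT10 RNAi and 0.13 with both constructs. It was 0.083 and 0.047 of the gap in peak input reads. The shares were 0.158 and 0.073 for peaks with an FDR under 0.05, and 0.123 and 0.095 for those with at least 100 input reads. A change of the whole gene would move its peaks and the gene alike. It would also leave as it was the ratio of IP to input reads, for which peaks were listed. Listing for that ratio can enlarge the input gap, so the shares do not measure how large a gene-level part is. A change in the reads captured by the antibody stays open: its share of the summed gaps was 0.164 and 0.18, but peaks were listed for their ratio of IP to input reads and held medians of 44 and 39 input against 167 and 173.5 IP reads, so that share decides nothing. Counting error of few input reads stays open, since 17.2% and 9.3% of listed peaks had an input change past a corrected Poisson test, and over the peaks with at least 100 input reads 56.8% and 40.5%. A difference between the genotypes themselves was not tested and may also be involved.

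Hsp70Bb was higher in every library of both RNAi genotypes than in any control library. A move of reads counted to the other near-identical Hsp70 copies is argued against. Their summed FPKM was only 23.7 in control and did not fall, but changed by 11.6 for NAT10 RNAi and 44.5 with both constructs. Reads that were given to no copy in control were not examined. The other 13 listed heat shock genes did not rise as a set for NAT10 RNAi, with a median of -0.7 (4 higher, 8 lower). That argues against a general heat shock response only if harvest at 72 h and 120 h did not lower these genes, which was not tested. Such a response stays open with both constructs, where the median was 0.03 (4 higher, 6 lower). Reads from an RNAi construct that carries Hsp70 sequence may contribute and cannot be told apart from a change of the gene, because the construct goes with the genotype. The lowest level in a library was 239.5 FPKM for NAT10 RNAi and 382.6 with both constructs.

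The NAT10 gene, l(1)G0020, was not lower in the libraries labelled NAT10 RNAi or NAT10 and Xrp1 RNAi. Reads of the construct counted to the gene may hide a fall. With both constructs the region of its listed peak held 1 input read, beside 1072 for the gene. In control it held 31, beside 922 (Fisher's exact test, two-sided, with the region taken as part of the gene, p = 5.6e-10). The authors counted the region reads per peak, while the gene reads were recovered from FPKM, so the former need not be part of the latter. That region was taken from the table of differential peaks, so it was picked for its change and the test decides nothing. A strain variant that keeps reads of the region from aligning could equally leave 1 read there, and strain and construct go with the genotype, so they cannot be told apart. For NAT10 RNAi the gene's log2 fold change was 0.1 and no peak of it was listed, so no region could be examined.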

How the results depend on the processing

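The fits by edgeR and DESeq2, the rescaled list tests and overlaps and the FDR threshold on peaks were chosen after seeing the data, and the other alternatives were set before. Of the combinations of main result and alternative, 119 were rated the same and 65 as moved. Counts of genes, lists, shared genes and peaks were rated the same within 1.5 times. Percentages of overlapping peaks were rated the same only within the 95% interval of their main value. Rank correlations were rated by their sign and test. For single lists 490 list results were the same, 52 were weaker, 37 stronger and 15 turned direction. For named genes 4454 were the same, 33 weaker, 5 stronger and 5 turned. These tallies exclude fits with 1 library left out, in which all 108 counts stayed within 1.5 times, 863 list results were the same, 14 weaker, 7 stronger and 7 turned, and 3390 named gene results were the same and 30 weaker. The cause of changes was not tested unless stated. Depth, 15518179 to 24272099 reads in genes, limits genes of low level and peaks of few input reads.

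For NAT10 RNAi against control, scaling moved the split of higher and lower genes. There were 3642 lower after rescaling, 3510 higher and 3834 lower by quantile normalization, 3783 lower by edgeR with TMM and 3887 with RLE, and 3473 higher and 3504 lower by DESeq2. Between the RNAi genotypes there were 3231 higher and 3207 lower after rescaling, 3236 and 3222 by quantile normalization, 3363 higher by TMM, 3505 higher and 3399 lower by RLE, and 3108 and 2885 by DESeq2. Asking for a 2-fold change, which by construction leaves fewer, gave 827 (586 higher, 241 lower), 197 (137, 60) and 512 (185, 327) genes. With a pseudocount of 0.1 these were 1210, 325 and 830, with 5 they were 419, 105 and 234, by edgeR with TMM 1277, 380 and 854 and by DESeq2 1284, 379 and 858. Rescaling split them into 419 higher and 351 lower, 136 and 64, and 263 and 234. At 2-fold there were 93 higher and 36 lower genes shared by the comparisons with control, and 261 and 144 opposed between NAT10 RNAi against control and both constructs against NAT10 RNAi. Without a fold limit the opposed genes numbered 2500 and 2433 after rescaling. The NAT10 gene, l(1)G0020, turned direction in NAT10 RNAi against control at -0.068 (rescaled), -0.105 (quantile), -0.059 (TMM), -0.072 (RLE) and -0.075 (DESeq2).

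An estimated correlation left 1, 0 and 4 lists, and fry, which tests another hypothesis, called 32 and 30 in the first and last comparison. Under fry the direction turned for NAT10 RNAi against control in lists of ATF4 (adjusted p = 0.00174), heat shock (0.00216), cell cycle (0.762), fat body (0.00527), cuticle (0.00025), insulin (0.00781) and neuron genes (0.00014). It turned for both constructs against control in JAK/STAT (0.562), and between the RNAi genotypes in ATF4 (0.00031), cell cycle (0.305), glue (0.641), digestive (0.013) and tracheal genes (0.00157). Rescaling turned cuticle in the first (0.851) and digestive genes in the last (0.607).

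Leaving out each library in turn gave 7036 to 8030 genes (5050 to 5715 higher, 1956 to 2315 lower) and 15 to 15 lists in NAT10 RNAi against control, 3843 to 4639 (2034 to 2677, 1740 to 2135) and 16 to 20 with both constructs against control, and 6316 to 7012 (1561 to 1800, 4750 to 5277) and 10 to 14 between the RNAi genotypes. Uncalled lists that turned direction ranged over adjusted p of 0.89 to 0.976 (neuron, NAT10 RNAi against control), 0.138 to 0.902 (cytosolic ribosomal proteins), 0.485 to 0.991 (tRNA synthetases) and 0.808 to 0.999 (JAK/STAT), the last 3 with both constructs against control. They turned without control replicate 3 or NAT10 RNAi replicate 2 (neuron), without replicate 1 (ribosomal proteins) or replicates 2 or 3 (synthetases) of the larvae with both constructs, and without control replicate 3 or replicate 2 with both constructs (JAK/STAT). Where 1 genotype is left with fewer libraries, its spread is pooled with the others.

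Replicate numbers did not pair the libraries: correlations of deviations lay between -0.066 and 0.076 for the same number and between -0.107 and 0.083 for others. A replicate block gave 7581, 4539 and 7016 genes. With both constructs against control the lists of Xrp1 partners (0.0556), ecdysone response (0.0519) and midgut genes (0.0556) were no longer called, and between the RNAi genotypes oxidative phosphorylation was (0.0394).

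The upper part of the authors' fold enrichment held 16487, 14386 and 15619 peaks in control, NAT10 RNAi and both constructs. Overlaps at 50% of both peaks and within that upper part were 53.7% and 50.9% (control in NAT10 RNAi), 51.3% and 52.7% (control in both constructs), 54.5% and 58.5% (NAT10 RNAi in control), 54.0% and 56.8% (NAT10 RNAi in both), 52.6% and 55.9% (both in control) and 54.5% and 52.6% (both in NAT10 RNAi). Stricter p left 843 (182 higher, 661 lower) and 827 (379, 448) differential peaks, with 19 higher and 114 lower genes shared, and an FDR under 0.05 left 166 (36, 130) and 204 (74, 130).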

Other observations

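The tests of this part, the other splits of the libraries, were chosen after the results were seen. AsnS, Ldh and mnd are members of the ATF4 list, and FASN1 and Desat1 of the late-larval fat body list, neither of which was called in NAT10 RNAi against control (camera adjusted p = 0.376 and 0.51). AsnS, which encodes asparagine synthetase, stood at 18.4 ± 0.615 FPKM in control, 5.68 ± 0.357 in NAT10 RNAi and 5.47 ± 0.704 with both constructs (SD, n = 3), and was lower than control in both (limma adjusted p = 4.84e-08 and 1.79e-07). Ldh, lactate dehydrogenase, was higher in both, at 82.2 and 73.1 FPKM against 23.8 (limma adjusted p = 3.66e-11 and 2.35e-10). The amino acid transporter gene mnd stood at 37.4 FPKM in control, 14.2 in NAT10 RNAi and 33.3 with both constructs, and differed between the RNAi genotypes (limma adjusted p = 1.78e-06). The lipid synthesis genes FASN1 and Desat1 were higher in NAT10 RNAi than in control by 1.39 and 1.17 on the log2 scale, and higher with both constructs by 0.93 and 0.30. These directions held under rescaling, quantile normalization, edgeR and DESeq2. Desat1 and mnd with both constructs against control were not followed under all of these. Harvest was at 72 h for control and 120 h for NAT10 RNAi.

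Glutathione S-transferase genes, whose products conjugate toxic compounds, include members that were higher in the libraries labelled NAT10 RNAi than in both other genotypes. GstE6 stood at 0.441, 4.19 and 0.246 FPKM in control, NAT10 RNAi and both constructs, and GstD9 at 4.72, 12.5 and 4.94 (limma adjusted p between the RNAi genotypes 1.26e-06 and 2.53e-06). With both constructs they did not differ from control by the test (limma adjusted p = 0.306 and 0.725). Gst genes of a cluster are similar in sequence, so the share of reads given to each is uncertain.

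With 3 libraries against 3 there are 10 splits, 1 of which is the real one, too few for a share under 0.05. Each other split mixes both genotypes on each side, so the difference between them enters the spread and leaves few calls. Counts of the other splits are therefore not what unchanged groups would give. The real split called 7653 genes in NAT10 RNAi against control, 4710 with both constructs against control and 7094 between the RNAi genotypes, and the highest of the other splits called 0 genes in each by limma, with at most 119, 662 and 223 genes at an unadjusted p under 0.05. It called 15, 19 and 12 gene lists, and the highest of the other splits 10, 12 and 10.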
